A study of Mus musculus with 8 samples.

How the data were processed

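The series measured messenger RNA of the posterior part of mouse embryos on Agilent whole mouse genome arrays with 2 colours, in Cdx2 null mutants against wild type embryos at 4/5 and at 7/8 somites. Per the labels' protocols, the tissue was kept in RNAlater, RNA was isolated with a RiboPure kit, and 300 ng of it was amplified linearly and labelled. Per the series' design text, 20 embryos of each genotype and stage gave the RNA, so each stage had 1 pool per genotype and the series had 4 pools. Each stage had 4 arrays, an original dye swap pair and a technical repeat of it. Arrays that carry the same 2 pools were averaged and counted as 1 replicate.

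The deposited scanner files hold 45018 spots per array. Spot and local background brightness are intensity values per the file headers, with no normalization. The scanner software's processed signals are intensity values that were background-subtracted, spatially detrended and dye-normalized, per the file headers. The scanner software's log ratio is the log10 of Cy5 over Cy3, per the file headers, and its flags mark spots that are saturated, uneven or well above background. The submitters' processing notes name Agilent Feature Extraction 9.5.3, whereas the file header gives version 10.5.1.1. The deposited series matrix holds log10 ratios of null over wild type. They equalled the scanner's log ratio, with its sign turned where the null pool carried Cy3, at 45018 of 45018 spots on each of the 8 arrays (tolerance 1e-05), and every column had a median of 0. Scale, centring and direction of the matrix are therefore known. All of its columns belong to this series.

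The direction of each ratio was taken from the genotype that the labels give for each channel, and every value below is null over wild type. Mean spot signals were corrected for local background with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the data.table package), with control spots at weight 0. Spots that the scanner marked for an uneven local background, 58 of them on array 1 of 4/5 somites, where 1 such background reached 103636, received the median background of their array before normexp. This step was added after seeing the data. Without it the standard deviation of log2 ratios on that array was 0.151 against 0.228 to 0.264 on the other 7 arrays, and with it 0.257. It raised the number of genes called over both stages from 945 to 1723. Spots marked as outliers were then left out (1309 in all, 0.377% of non-control spots), and no non-control spot was marked as saturated. Spots of a probe were averaged. Of 41174 probes, 21907 were kept because they were well above background in the channel of 1 genotype on at least 3 of the 4 arrays of a stage. Control spots and probes below that limit were left out.

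Probes were named through accessions in the RefSeq table of assembly GRCm38.p6, which matched 25097 probes (16875 of those kept), and otherwise by the name in the files. Probe positions are those of the files, on build mm9. The brightest probe stood for each gene, which left 15490 genes, 2676 of them without a symbol. Other probes are mentioned for some genes where they differ from the one used. A probe that was not well above background in 1 genotype on all arrays of a stage gives only a bound, computed once per stage from channel values after loess and Aquantile normalization, with the lowest signal among probes well above background standing in for a dimmer one.

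Genes changed over both stages were called with limma on 2 values per gene, 1 per stage (each the mean of 4 arrays), with lmFit, eBayes and a Benjamini-Hochberg adjusted p of at most 0.05, two-sided. This test has 1 residual degree of freedom per gene plus a prior of 22.74 degrees of freedom (prior standard deviation 0.123), so its p-values rest mainly on a spread shared across genes. They measure the spread between the pools of the 2 stages. Within a stage there is no second pool, so genes at least 2-fold different with the same sign on all 4 arrays are listed by size with no p. A stage difference needed stage means at least 2-fold apart and no overlap of arrays. The wild type stages were compared by the same size rule on channel values after loess and Aquantile. The 30 gene lists were tested with limma's camera (preset correlation 0.01, lists with at least 3 measured genes), with an estimated correlation and with fry beside it, and by the percentile of the list median among 10000 random lists matched on intensity. Groups, tests, gene lists and the rule for named genes were fixed before the data were examined.

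Named genes are Cdx1, Cdx2 and Cdx4, the 12 largest rises and the 12 largest falls among genes called with the same sign on all 8 arrays, the 4 largest further genes per stage and direction, the 5 largest stage differences each way, up to 4 members of each list with the largest mean ratio, and up to 4 members of each list with at least 3 genes past the wild type size rule. Transcripts without a symbol are counted only. Other names were chosen after their values were seen and are given as such.

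The steps were tested on simulated scanner signals. For genes changed over both stages, 49 of 50 genes simulated at 1.5-fold and 50 of 50 at each of 2-, 3- and 4-fold were called, with 2 of 15215 unchanged genes. The size rule listed 30 of 50 genes simulated at 2-fold at 4/5 somites and 31 of 50 at 7/8 somites, and 50 of 50 at 3- and at 4-fold at each stage, with 0 of 15155 unchanged genes. It found 60 of 60 simulated 4-fold stage differences, and 57 of 60 simulated 4-fold changes between wild type stages. A list of 15 genes shifted by 0.40 was called by camera and by neither the estimated correlation nor fry, and 0 of 29 unshifted lists were called. The simulated genes varied independently of each other, with a spread drawn from the prior of the fit. The counts of false calls therefore do not cover lists whose genes vary together, nor a spread unlike that prior. The arrays lie on 2 slides, each with 1 dye swap pair of each stage, so slide was used as a block and each slide was also analysed alone. Alternatives covered background, normalization, the series matrix, the filter on dim probes, the probe per gene, arrays left out, the variance prior, thresholds and the replicate unit. The number of pools limits the precision throughout.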

Results

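The posterior part of mouse embryos of the strain C57Bl6J/CBA was compared between Cdx2 null mutants and wild type at 4/5 and at 7/8 somites. Cdx2 encodes a homeodomain transcription factor of the caudal embryo. The tissue taken ran from behind the youngest somite to where the allantois begins, and 20 embryos were pooled per genotype and stage. The 2 pools of a stage were hybridized together on 4 arrays, with Cy3 on the null pool on 2 of them and Cy5 on the others. Between 46.5% and 58.9% of probes were well above background per channel and array. Across genes, log2 ratios correlated at r = 0.868 to 0.925 between arrays of the same stage and dye order, at 0.488 to 0.57 between arrays of the same stage with dyes swapped, at 0.511 to 0.631 between stages with the same dye order and at 0.283 to 0.367 between stages with dyes swapped, so dye order weighed about as much as stage (genes are not independent replicates). Standard deviations given for a stage are those of its 4 arrays and are technical.

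The mutated gene itself and its paralogues come first. Cdx2 was lower in the null pool on all 8 arrays, with log2 ratios from -1.61 to -1.10. Its mean was -1.23 ± 0.12 (SD of 4 arrays) at 4/5 somites and -1.55 ± 0.05 at 7/8 somites, a 2.62-fold fall over both stages (SE 0.09 on the log2 scale, n = 2 stages, adjusted p = 1.59e-10). The probe lies on chromosome 5 at 148112547 to 148112606 (mm9). Whether it lies in the part removed from the mutant allele is not given in the sources used here, so its value does not settle the genotype labels. Cdx4 also fell, by 0.74 (SE 0.09, adjusted p = 3.63e-06), with -0.94 at 4/5 and -0.55 at 7/8 somites. Cdx1 did not pass the test (mean 0.02, SE 0.12, adjusted p = 0.953), with -0.36 ± 0.07 at 4/5 and 0.40 ± 0.03 at 7/8 somites. The list of the 3 Cdx genes moved down by camera (adjusted p = 0.000295, adjusted p = 0.621 with an estimated correlation), with 2 of 3 genes fallen over all genes tested and 2 adjusted over the list alone, but it holds the mutated gene itself, so its shift is no separate finding.

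The first question was which genes differed between null and wild type pools over both stages. Nepn, which encodes a secreted leucine-rich repeat protein (chromosome 10 at 52124110 to 52124169), fell most, by 2.44 on the log2 scale (SE 0.10, adjusted p = 8.98e-14). Apart from Cdx2 and the Hox genes, the chemokine gene Cxcl12 fell by 2.24 (SE 0.10) and the clotting factor gene Vwf by 1.65 (SE 0.09), followed by Saa3 (-1.56), Sparcl1 (-1.51), the keratin gene Krt19 (-1.37), Rgn (-1.31) and Prpf19 (-1.30). The T-box gene Tbx1 (chromosome 16 at 18581816 to 18581875) rose most, by 1.68 (SE 0.09, adjusted p = 1.78e-12). The collagen gene Col26a1 rose by 1.48 (SE 0.09), and Lratd1 (1.42), Adamts2 (1.37), the placental prolactin gene Prl4a1 (1.37), Fgfbp3 (1.35), Krt23 (1.33), the amino acid transporter genes Slc7a7 (1.29) and Slc7a8 (1.24), Minar2 (1.29), Cdc42ep1 (1.28) and the zinc finger gene Snai2 (1.27) were the other largest rises, each on all 8 arrays. Saa3 was not well above background in the null pools and was at least 2.46-fold and at least 2.98-fold lower there at 4/5 and 7/8 somites. At 7/8 somites wild type was well above background on only 2 of 4 arrays for Tbx1 and Minar2 and on 3 for Lratd1. For Minar2 it was so on 3 of 4 arrays at 4/5 somites. The sizes of these rises are therefore uncertain. The other probe of Cxcl12, a dimmer one, read -0.71, and those of Adamts2 and Cdc42ep1 also gave smaller values, 0.47 to 0.67 for Adamts2 and 0.48 for Cdc42ep1. Prpf19 had array standard deviations of 0.78 and 0.27. At 4/5 somites it read -0.31 and -0.43 with Cy3 on the null pool, against -1.79 and -1.64 with Cy5, so its size there depended on dye order.

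In all, 1723 of 15490 genes changed, 1019 up and 704 down, 1501 of them with the same sign on all 8 arrays and 53 by at least 2-fold (26 up, 27 down). Within slide 1 alone the count was 1429 and within slide 2 alone 1556, and with slide as a block on the 4 dye swap pairs, which leaves only technical spread, it was 9814. The count fell to 784 without array 3 of 4/5 somites and to 1129 without array 2, to 945 when spots with an uneven background kept it, to 488 with no background correction, to 486 with median centring (75.1% up against 59.1%) and to 774 with no filter on dim probes. The stages' ratios correlated across genes at r = 0.608.

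**Figure D1:**
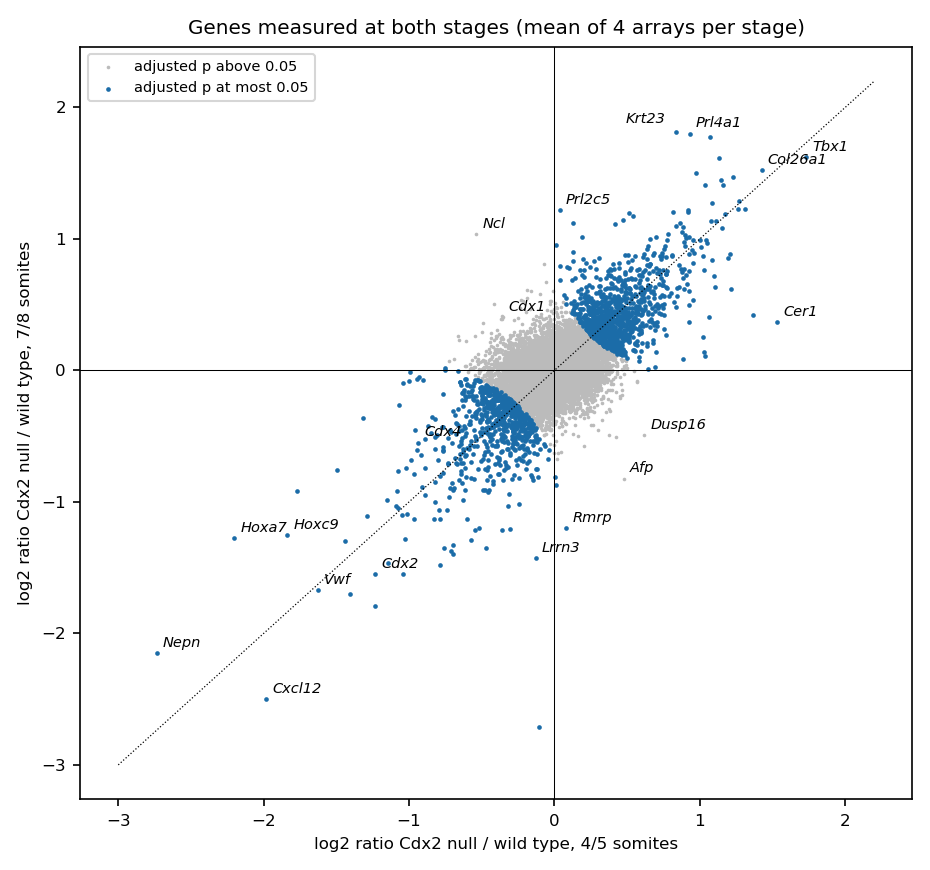
Log2 ratio of Cdx2 null over wild type at 4/5 somites (horizontal axis) against 7/8 somites (vertical axis), 1 point per gene (mean of 4 arrays per stage), with the 1723 genes changed over both stages in blue and the dotted line marking equal ratios. Nepn, Cxcl12 and Vwf lie far down at both stages, Tbx1 and Col26a1 far up, and Ncl, Afp, Rmrp and Dusp16 lie away from the dotted line.

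The title of the series names Cdx and Hox genes and Wnt signalling in the posterior growth zone, and these groups were fixed as lists. Hox genes of the middle paralogue groups 5 to 9 were lower in the null pools. Of 14 measured, 9 fell and 2 rose (adjusted over the list alone, 10 fell and 2 rose). Hoxa7 (chromosome 6 at 52165626 to 52165685) fell by 1.74 (SE 0.13, adjusted p = 7.83e-10), with -2.20 ± 0.20 at 4/5 and -1.27 ± 0.09 at 7/8 somites. Hoxc9 fell by 1.55 (SE 0.10), Hoxb9 by 1.34 (SE 0.12) and Hoxc6 by 1.12 (SE 0.11). The second probe of Hoxb9 read -1.86 at 4/5 and -3.06 at 7/8 somites where the probe used here read -1.77 and -0.91, so its size is uncertain. Within this list Hoxa5 and Hoxb5 rose, with 0.75 and 0.28 (named here after their values were seen). The list moved down by camera (adjusted p = 2.86e-09, adjusted p = 0.621 with an estimated correlation).

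Of the 4 measured Hox genes of groups 10 to 13, 3 fell and adjusted over the list alone 4 did, and the list moved down (camera adjusted p = 1.56e-06, adjusted p = 0.621 with an estimated correlation). Hoxa10 fell by 0.98 (SE 0.09), Hoxd13 by 0.69 (SE 0.10) and Hoxa11 by 0.53 (SE 0.09), while Hoxd10 did not pass (-0.25, adjusted p = 0.0687). Hoxd13 was not well above background in the null pools and was at least 1.30-fold and at least 1.65-fold lower there at the 2 stages. Groups 1 to 4 did not pass as a list (camera adjusted p = 0.0626). Among their genes Hoxd4 fell by 1.16 (SE 0.09) and Hoxd1 by 0.41 (SE 0.09), the 2 that fell also adjusted over the list alone, and Hoxb1 did not pass (-0.22).

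**Figure D2:**
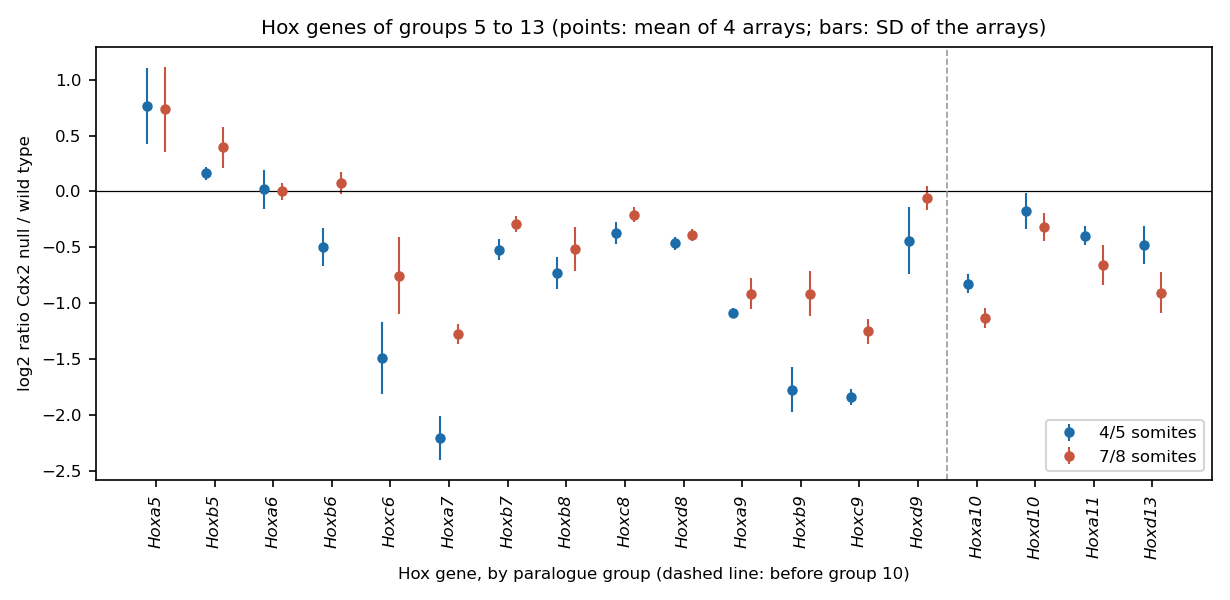
Log2 ratio of Cdx2 null over wild type (vertical axis) for each measured Hox gene of groups 5 to 13 (horizontal axis, by paralogue group), at 4/5 somites (blue) and 7/8 somites (red). Points are means of 4 arrays, bars their standard deviation, and a dashed line stands before group 10. Hoxa7, Hoxb9 and Hoxc9 lie lowest at 4/5 somites and Hoxa5 highest.

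Genes of retinoic acid metabolism and response were mostly higher in the null pools. Of 14 measured, 9 rose and 3 fell, with the same counts adjusted over the list alone. Aldh1a2, which encodes a retinoic acid synthesizing enzyme, rose by 1.06 (SE 0.09, adjusted p = 7.40e-09), the receptor gene Rarb by 0.76 (SE 0.09) and Stra8, induced by retinoic acid, by 0.68 (SE 0.09). In the wild type channels Aldh1a2 was itself lower at 7/8 than at 4/5 somites (-1.69 on the log2 scale). Cyp26a1, which encodes an enzyme that degrades retinoic acid, fell by 0.82 (SE 0.09, adjusted p = 2.56e-07). The list moved up by camera (adjusted p = 0.000848, adjusted p = 0.621 with an estimated correlation).

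Wnt ligands, regulators and targets moved both ways. Of 25 measured, 4 rose and 5 fell, also adjusted over the list alone. The list did not pass over both stages (camera adjusted p = 0.856, median 0.07, mean -0.02). Its median was -0.08 at 4/5 and 0.16 at 7/8 somites, at percentiles 3.2 and 100 of the random lists. The values of the stages thus partly cancel in the mean, and their difference was not tested. Rnf43, which encodes a ubiquitin ligase that removes Wnt receptors, fell by 0.91 (SE 0.09) and Wnt5b by 0.66 (SE 0.09), while Nkd1, which encodes a Wnt pathway inhibitor, rose by 0.73 (SE 0.09). Of 14 FGF pathway genes 2 rose and 4 fell (5 fell adjusted over the list alone, camera adjusted p = 0.251), with a list median of -0.25 at 4/5 and 0.19 at 7/8 somites. Dusp4, a phosphatase gene of the FGF response, fell by 1.07 (SE 0.09), Etv4 by 0.66 (SE 0.12) and Fgf18 by 0.32 (SE 0.09), and Dusp6 rose by 0.44 (SE 0.09).

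Among genes of the forming mesoderm, several somite genes rose. Of 6 measured somite genes 3 rose (4 adjusted over the list alone) and none fell. Meox1 rose by 0.92 (SE 0.10), Tcf15 by 0.58 (SE 0.12) and Foxc2 by 0.49 (SE 0.12). Their ratios were larger at 4/5 somites (1.22, 1.03 and 0.88) than at 7/8 somites (0.62, 0.14 and 0.09), a difference without a test. The somite list moved up (camera adjusted p = 0.00465, adjusted p = 0.621 with an estimated correlation). Its adjusted p was 0.0792 with no background correction and 0.0669 with no filter on dim probes. Among 15 presomitic mesoderm and segmentation clock genes 5 rose and 4 fell (6 and 5 adjusted over the list alone). Cer1 rose by 0.95 (SE 0.15), Pcdh8 by 0.89 (SE 0.13) and Mesp1, expressed where somites form, by 0.88 (SE 0.09), while Msgn1, expressed in presomitic mesoderm, fell by 0.60 (SE 0.10). The median of this list was -0.13, its mean 0.11, and it did not pass (camera adjusted p = 0.588). Of 15 axial progenitor and tail bud genes 4 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.0924), and the list median was -0.25 at 4/5 and 0.12 at 7/8 somites. T, the gene of brachyury, fell by 0.34 (SE 0.10), with -0.61 at 4/5 and -0.07 at 7/8 somites, and Evx1 by 0.33 (SE 0.11) and Gdf11 by 0.28 (SE 0.09). These calls are fragile, as T lost its call in 20 of 26 other settings, Evx1 in 21 of 26 and Gdf11 in 12 of 25, and so did Foxc2 in 11 of 26.

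Of 10 notochord and node genes 4 fell (5 adjusted over the list alone), and the list moved down (camera adjusted p = 0.000595, adjusted p = 0.621 with an estimated correlation). Tekt1 and Cfap126, which encode proteins of cilia, fell by 0.68 (SE 0.09) and 0.37 (SE 0.09) and Shh by 0.60 (SE 0.09). T and Shh stand in other lists as well. Of 13 endothelial genes 4 fell and 1 rose (6 and 2 adjusted over the list alone), and this list moved down (camera adjusted p = 0.00414, adjusted p = 0.658 with an estimated correlation). Etv2, a regulator of the endothelial lineage, fell by 1.01 (SE 0.11), Kdr, which encodes a receptor of vascular endothelial growth factor, by 0.88 (SE 0.11), Tal1 by 0.43 (SE 0.12, a call lost in 18 of 26 other settings) and Egfl7 by 0.41 (SE 0.09). The endothelial median was -0.04 at 4/5 and -0.27 at 7/8 somites. Of 11 allantois genes 6 rose and 1 fell (7 and 3 adjusted over the list alone), and the list moved up (camera adjusted p = 0.00849, adjusted p = 0.621 with an estimated correlation). Snai2 leads it, Ahnak rose by 0.80 (SE 0.09, with -0.03 to 0.91 on its 4 other probes) and Postn by 0.44 (SE 0.11, a call lost in 11 of 26 other settings), and Bmp4 fell by 0.49 (SE 0.09). The allantois list lost its call with no background correction (adjusted p = 0.063), median centring (0.0943) and slide as a block (0.0693).

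Markers of other tissues of the embryo and its membranes moved too. Of 14 visceral endoderm genes 7 rose and none fell (8 and 0 adjusted over the list alone). Cubn, which encodes the endocytic receptor cubilin, rose by 1.18 (SE 0.09), its partner gene Amn by 0.97 (SE 0.09), and the apolipoprotein genes Apoe by 0.96 (SE 0.09) and Apom by 0.43 (SE 0.09). The list moved up (camera adjusted p = 5.73e-08, adjusted p = 0.621 with an estimated correlation), with a median of 0.47 at 4/5 and 0.16 at 7/8 somites. Of 10 surface ectoderm genes 4 rose (5 adjusted over the list alone), with Krt5 at 0.92 (SE 0.09), Wnt6 at 0.61 (SE 0.09), Grhl2 at 0.34 (SE 0.08) and Gata3 at 0.30 (SE 0.08, a call lost in 10 of 26 other settings). This list moved up (camera adjusted p = 0.00739, adjusted p = 0.621 with an estimated correlation), and its adjusted p was 0.0513 with slide as a block. Of 6 trophoblast genes 3 rose and 1 fell (4 and 1 adjusted over the list alone). Prl3d1 rose by 0.58 (SE 0.09), Rhox6 by 0.52 (SE 0.10) and Elf5 by 0.51 (SE 0.09), and Plac1 fell by 0.33 (SE 0.09, a call lost in 9 of 26 other settings). The trophoblast list moved up (camera adjusted p = 0.0269, adjusted p = 0.621 with an estimated correlation), a call lost under 6 further settings with adjusted p from 0.0522 to 0.167. Of 19 gut endoderm genes 7 rose and 4 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.487). Spink1 rose by 0.74 (SE 0.09) and Sox17 by 0.58 (SE 0.09, 0.29 on its other probe), and Krt19 and Shh fell. Pools can differ in sex. Xist, expressed from the inactive X chromosome, fell by 0.54 (SE 0.09, adjusted p = 9.09e-05; -0.36 to -0.04 on its 3 other probes) and the Y-linked Eif2s3y rose by 0.37 (SE 0.10, adjusted p = 0.0108, a call lost in 10 of 26 other settings), while the Y-linked Ddx3y (0.03) and Kdm5d (0.23) did not pass.

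**Figure D3:**
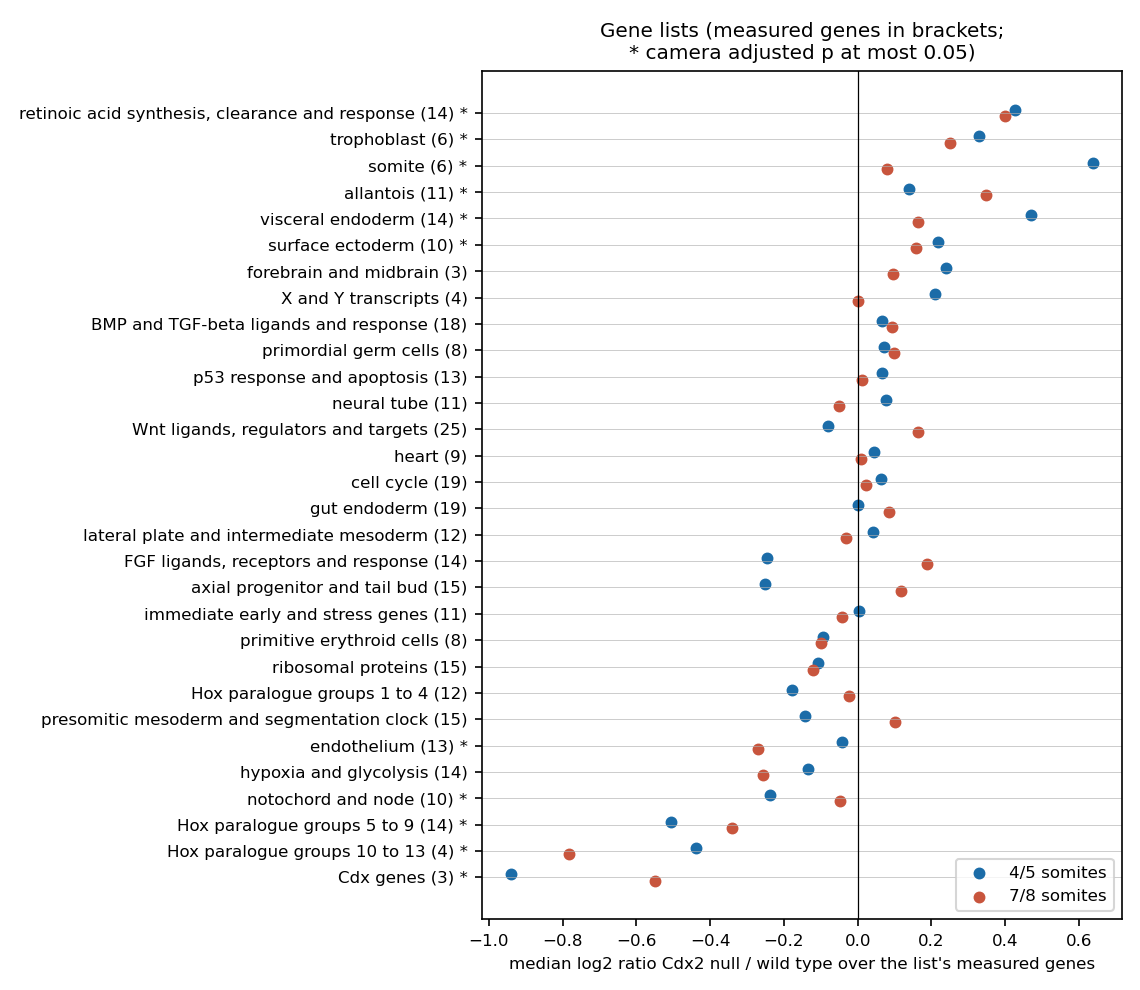
Median log2 ratio of Cdx2 null over wild type (horizontal axis) over the measured genes of each of the 30 lists, at 4/5 somites (blue) and 7/8 somites (red), with the number of measured genes in brackets. The 11 lists with a star passed camera, 6 of them up and 5 down, with the Cdx and the later Hox lists lowest.

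Of the 30 lists 11 passed camera, 6 up and 5 down, and 0 did with an estimated correlation or by fry, which had 1 residual degree of freedom. At an unadjusted p under 0.05 camera gave 16 lists, the estimated correlation 0 (lowest p = 0.108) and fry 3 (lowest p = 0.0213). The medians of 9 lists lay outside the central 95% of random lists on the same side at both stages, 8 of them among the 11. The somite, notochord and node, and endothelium lists did not. The FGF, presomitic mesoderm, and axial progenitor and tail bud lists lay below that range at 4/5 and above it at 7/8 somites. With slide as a block 8 passed, within slide 1 alone 14 and within slide 2 alone 11.

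At 4/5 somites alone, 60 genes were at least 2-fold different with the same sign on all 4 arrays, 34 higher and 26 lower in the null pool. With 1 pool per genotype there is no test within a stage. The largest not named above were Dmrt2, a gene of the dermomyotome (1.21 ± 0.19, SD of 4 arrays), on the higher side with Cer1 (1.53 ± 0.22), Pcdh8 (1.37 ± 0.11) and Meox1 (1.22 ± 0.02), and Thumpd1 (-1.32 ± 0.12) and the hormone gene Sct (-1.29 ± 0.08) on the lower side with Hoxc6 (-1.49 ± 0.32) and Dusp4 (-1.15 ± 0.21). Dmrt2 was well above background in wild type on 3 of these 4 arrays. At 7/8 somites 79 genes passed the same size rule, 40 higher and 39 lower. The cartilage collagen gene Col2a1 (2.84-fold), Smpd3 (1.41 ± 0.10, with 0.41 and 1.32 on its other probes), Cubn (1.28 ± 0.29) and Ism1 (1.22 ± 0.08) were higher, and Rab32 (-1.48 ± 0.10), Lrrn3 (-1.43 ± 0.14), the hormone gene Cck (-1.40 ± 0.13) and Krtap17-1 (-1.37 ± 0.03) lower. At both stages 33 genes passed, 16 higher and 17 lower. The scanner's processed signals gave 257 and 282 genes, no background correction gave 30 at 4/5 somites, and keeping uneven backgrounds gave 28 there.

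A further question was whether the null over wild type ratio differed between stages. Ncl, which encodes the nucleolar protein nucleolin, had a ratio of -0.54 ± 0.07 at 4/5 and 1.04 ± 0.08 at 7/8 somites on a bright probe (chromosome 1). A second Ncl probe had the same signs (-0.54 at 4/5 somites), but its position overlaps that of the probe used, so it is no independent reading. The 2 others, elsewhere in the gene, showed no such change and gave 0.08 and 0.05, and 0.23 and 0.09. The placental prolactin gene Prl2c5 was also higher at 7/8 somites (0.04 ± 0.08 against 1.22 ± 0.14), while its second, dimmer probe gave 0.08 and 0.69, less than 2-fold apart. Afp, the alpha-fetoprotein gene (0.48 ± 0.08 against -0.82 ± 0.10), Rmrp, an RNA component of a ribonuclease (0.08 ± 0.04 against -1.20 ± 0.19), Dusp16 (0.62 ± 0.08 against -0.49 ± 0.13), Lrrn3 (-1.43 ± 0.14 at 7/8 somites) and Cer1 were lower. Lrrn3 was close to background in both pools at 4/5 somites, so the size of its stage difference is not known. Cer1 was well above background in wild type on only 2 of the 4 arrays of 7/8 somites. Its ratio there (0.37) and the size of its stage difference are therefore uncertain too. The rule took 8 genes in all, 2 higher and 6 lower at 7/8 somites, 1 of them without a symbol, and no pool was replicated within a stage.

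**Figure D4:**
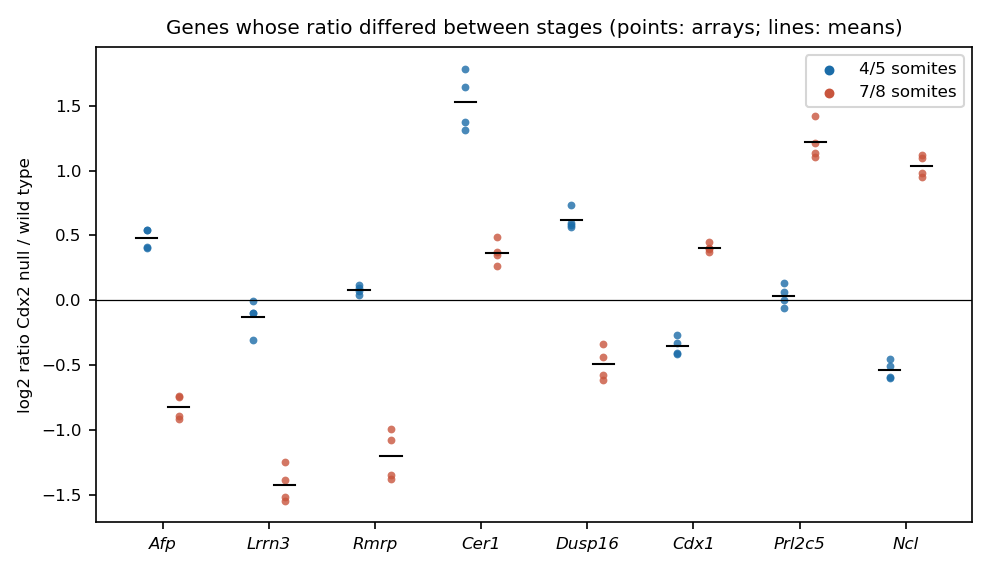
Log2 ratio of Cdx2 null over wild type (vertical axis) on each array (points) with stage means (lines), at 4/5 somites (blue) and 7/8 somites (red), for the 7 named genes whose ratio differed between stages and Cdx1. Ncl changes from -0.54 to 1.04 and Afp from 0.48 to -0.82.

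The wild type channels were compared between stages for context, with values only. Haemoglobin genes of primitive red cells were higher at 7/8 somites, Hbb-bh1 by 3.57 and Hbb-y by 1.13 on the log2 scale, with 3.91 and 1.05 in the null channels. Hba-x was higher too, by an unknown size since it was close to background at 4/5 somites. Of 15 axial progenitor genes 3 were lower by the size rule (list median -0.10), Fst at -1.67, Wnt8a at -1.55 and Cdx1 at -1.10, against -1.29, -1.09 and -0.34 in the null channels. By the size rule 14 genes were higher and 25 lower at 7/8 somites in wild type, 20 and 25 in the null pools, and 5 and 13 in both. The count of 39 in wild type became 64 on slide 2 alone and 175 with the scanner's processed signals.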

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

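The tests of added visceral endoderm tissue below were chosen after the results were seen, and those of randomly turned signs and of normalization were chosen before.

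For 6 of the 149 named genes the ratio had opposite signs at the 2 stages on all arrays, and this difference was not tested, since each stage has 1 pool per genotype. The nucleolin gene Ncl was 1.575 higher on the log2 scale at 7/8 than at 4/5 somites. This was seen on 2 of its 4 probes, which overlap in position, and not on the other 2. Afp differed by -1.299, Rmrp by -1.28 and Dusp16 by -1.112. Ncl, Afp, Rmrp and Dusp16 were named for their large stage difference, so their place here follows in part from that choice. Cdx1, a paralogue of the mutated gene, went from -0.357 to 0.405, a difference of 0.7613, and Fst from -0.174 to 0.209, a difference of 0.3828.

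A single array stood apart from the other 3 of its stage in 7 of 298 groups of 4 arrays. Chance marks about 1 in 20 groups of independent arrays, but these arrays fall into 2 dye orders, so that share is only a guide. These were Fgfbp3 on array 2 of 4/5 somites (1.107 against 1.25 to 1.28), Cyp26a1 on array 4 of 4/5 somites (-0.9307 against -0.882 to -0.879), Dusp4 on array 2 of 7/8 somites (-0.8471 against -1.05 to -1.02), Cck on array 4 of 7/8 somites (-1.198 against -1.47 to -1.44), Nkx6-1 on array 4 of 7/8 somites (0.1542 against 0.939 to 0.996), Tnni1 on array 2 of 7/8 somites (0.06868 against 0.350 to 0.401) and Tbx5 on array 4 of 7/8 somites (-0.111 against 0.243 to 0.288).

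The count of 1723 genes changed over both stages was set against the count after turning the sign of 1 stage. Of these 2 splits, 1 gave as many genes as the real signs, namely the real one, and the other gave 0. With 2 splits no share under 0.05 can be reached.

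Visceral endoderm markers were higher in the null pools, and Afp, a marker of the same list, was among the genes of opposite sign. The list median stayed between 0.23 and 0.368 under 6 other background corrections and normalizations, which argues against these as the cause. More visceral endoderm tissue in the null pool would raise all of its abundant transcripts. At 4/5 somites 0 of the 5 brightest members in wild type (Apoe, Rbp4, Apoc2, Apom and Afp) lay below 0 on all 4 arrays and 5 lay above. Their ratios ran from 0.17 (Rbp4) to 0.87 (Apoe). These genes belong to the list called on the same values, so the count adds little. Added tissue stays possible at that stage. At 7/8 somites 1 of the 5, Afp, lay below 0 on all arrays at -0.82 and 3 lay above, so that tissue share and a change of single genes cannot be told apart there, and a biological effect of the genotype on this tissue stays open at both stages, untested.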

How the results depend on the processing

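The settings that keep uneven backgrounds or use 1 slide alone, and for gene lists the other background and normalization settings, the strict filter and the slide block, were chosen after seeing the data, and so was the main treatment of uneven backgrounds. The cause of each shift below was not tested unless stated. The 1723 genes changed over both stages became 488 with no background correction, 486 with median centring, 945 with uneven backgrounds kept, 774 with no filter on dim probes (more genes tested), 53 with at least 2-fold required, and 3031 with arrays as samples and stage as a random block (correlation 0.409). Tests of technical spread alone gave 9619 (4 dye swap pairs), 9814 (slide as a block) and 8356 (8 arrays). Leaving out an array or dye swap pair gave 784 to 1636, lowest without array 3 of 4/5 somites, and 1129 without its array 2. All 945 and all 784 genes were among the 1723. The 60 genes at 4/5 somites became 30 with no background correction, 28 with uneven backgrounds kept, 257 with processed signals and 257 with the series matrix, 354 at 1.5-fold, 7 at 3-fold and 8564 by limma on the 4 arrays. With uneven backgrounds kept 42.9% were higher against 56.7%. The 79 genes at 7/8 somites became 282 with processed signals, 281 with the series matrix, 404 at 1.5-fold, 11 at 3-fold and 7951 by limma on the 4 arrays. With median centring 67.7% were higher against 50.6%. The 8 stage differences became 5 with no background correction, 9 with uneven backgrounds kept, 85 with processed signals, 84 with the series matrix, 14 with every probe counted, 155 at 1.5-fold, 1 at 3-fold and 5038 by limma on 8 arrays. With median centring 66.7% were higher, and with uneven backgrounds kept 55.6%, against 25%.

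Of the 11 lists called, 0 remained with an estimated correlation and 0 by fry (0 and 3 of 30 lists at an unadjusted p under 0.05), while the other settings called 8 to 14. The share of called lists that moved up, 54.5% in the main setting, was 33.3% with no background correction and 36.4% with median centring. It was also 33.3% with no filter on dim probes, 37.5% with slide as a block, 42.9% on slide 1 alone and 45.5% with uneven backgrounds kept. In the remaining settings that called lists it was 54.5% to 60%. The 39 wild type stage genes became 175 with processed signals, 231 at 1.5-fold and 64 on slide 2 alone, and the 35.9% higher among them became 53.7% on slide 1 alone. Of 3851 values of the 149 named genes under the alternatives, 3440 kept their direction and side of the threshold, 355 lost the call, 49 gained it, 7 without a call changed sign and 0 called values were reversed. For 57 genes nothing changed in any setting. Median centring moved the median of all genes most, to 0.0797 at 7/8 somites. A probe not well above background in 1 genotype on all arrays of a stage gives only a bound on the ratio. Every ratio is paired, null over wild type on the same array, with slide or stage as a block where stated.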

Other observations

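The tests of younger embryos, of trophoblast tissue and of a dye effect or a single array below were chosen after the results were seen.

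Several groups not yet described held changed genes without passing camera as lists. Of 14 genes of hypoxia and glycolysis 3 rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.078). The glucose transporter gene Slc2a1 rose by 0.78 (SE 0.09) and Adm by 0.45 (SE 0.09), while Bnip3 fell by 0.60 (SE 0.09) and the glycolytic enzyme gene Eno1 by 0.45 (SE 0.09). Of 13 genes of the p53 response 2 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.162), with Phlda3 at 0.78 (SE 0.09), Trp53inp1 at 0.48 (SE 0.09, -0.06 on its other probe) and Sesn2 at -0.36 (SE 0.09, -0.06 on its other probe), and Cdkn1a not passing at 0.26. Of 18 genes of BMP and TGF-beta signalling 5 rose and 3 fell (5 and 5 adjusted over the list alone, adjusted p = 0.58), with Lefty2 at -0.51 (SE 0.09), Id4 at 0.40 (SE 0.08) and Nodal at 0.36 (SE 0.11, a call lost in 19 of 26 other settings). Of 11 neural tube genes 3 rose and 2 fell (3 and 3 adjusted over the list alone, adjusted p = 0.568). Zic1 rose, at least 1.49-fold at 4/5 and at least 1.82-fold at 7/8 somites since it was not well above background in wild type, Nkx6-1 rose by 0.56 (SE 0.09) and Nkx6-2 by 0.38 (SE 0.09), and Ncam1 fell by 0.54 (SE 0.09, with -0.76 to -0.04 on its 5 other probes). Of 8 germ cell genes 2 rose, Dppa3 by 0.84 (SE 0.09) and Alpl by 0.34 (SE 0.09), and Kit (-0.25) and Tfap2c (0.25) did not pass over all genes (3 rose and 1 fell adjusted over the list alone, adjusted p = 0.0937).

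Of 12 genes of lateral plate and intermediate mesoderm 2 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.795), with Gata6 at 0.54 (SE 0.10, -0.02 on its other, dim probe), Gata5 at 0.29 (SE 0.08, a call lost in 10 of 25 other settings) and Osr1 at -0.78 (SE 0.09). Of 8 primitive erythroid genes Hbb-bh1 fell by 0.39 (SE 0.09), also adjusted over the list alone, and 7 did not pass (adjusted p = 0.139). Of 11 immediate early and stress genes Atf3 rose by 0.49 (SE 0.09) and Jun by 0.37 (SE 0.09) and Hspa1a fell by 0.31 (SE 0.09), also adjusted over the list alone (adjusted p = 0.588, median -0.05, mean 0.05). Of 3 measured forebrain and midbrain genes En2 rose by 0.81 (SE 0.11), also adjusted over the list alone (adjusted p = 0.0893). None of 9 heart genes and none of 15 ribosomal protein genes passed, over all genes or adjusted over the list alone (adjusted p = 0.588 and 0.0836). Of 19 cell cycle genes Mcm2 fell by 0.30 (SE 0.10) over all genes, a call lost in 21 of 26 other settings, and none passed adjusted over the list alone (adjusted p = 0.88). The 4 X and Y transcripts did not pass as a list (adjusted p = 0.795), with 1 risen and 1 fallen (2 and 1 adjusted over the list alone).

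Of 14 genes higher at 7/8 somites in wild type 13 were lower in the null pools, and of 25 genes lower at 7/8 somites 20 were higher. Genes reported above are among them, with wild type log2 differences (7/8 minus 4/5 somites) of 1.45 for Hoxc9 and -1.69 for Aldh1a2. Mesp1 (-1.18), Cubn (-1.16) and Slc7a8 (-1.07) are others. A candidate explanation of these counts is that null embryos were younger than their somite count. If so, stage and genotype cannot be told apart for these genes. Slopes of the null over wild type ratio on the wild type stage difference were -0.256 (SE 0.0939) for the rising and -0.198 (SE 0.0775) for the falling genes, a difference of -0.0574 (SE 0.122). Both quantities share the wild type channels, whose noise pushes the slope up at 4/5 and down at 7/8 somites. At 4/5 somites alone, over genes well above background on all arrays, the slopes were -0.169 (SE 0.115, 12 genes) and -0.158 (SE 0.102, 20 genes), each within 2 SE of 0, so the test cannot tell. Younger embryos, the wild type pools themselves and an effect of the genotype on these genes all stay open. Over all genes r was -0.137. The slope of the falling genes corresponds to a rise of the visceral endoderm list by 0.128, where 0.276 was observed. That slope was fitted to these same ratios, and its genes include Cubn and Apoc2 of the list. The value of 0.128 is thus no separate prediction and does not test a delay.

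Placental prolactin genes and Krt23 were higher in the null pool at 7/8 somites. Of 8 measured prolactin family genes 7 lay above 0 on all 4 arrays there and 4 did at 4/5 somites, against 21.9% and 22.4% of all genes, and 2 of the 8 were not well above background at 7/8 somites. This family was looked at after its values were seen. Whether probes of related members also read each other's transcripts was not checked, so these genes may not be separate readings. The named genes gave Prl4a1 at 1.80 ± 0.11, Prl2c5 at 1.22 ± 0.14 (over both stages a call lost in 12 of 26 other settings), Prl3d1 at 0.77 ± 0.19 (SD of 4 arrays) and Krt23 at 1.82 ± 0.11. Over the 3 family genes outside the named ones that were well above background the lowest of the 4 array medians was 0.826 and the highest 0.931. These 3 were Prl2c3 (1.12 ± 0.14), Prl3d2 (0.85 ± 0.05) and Prl3b1 (-0.09 ± 0.07). Prl3b1 did not rise, so the medians mainly follow Prl3d2. Each dye order has 2 of these arrays and a dye effect would turn the sign between them. For Prl2c3 and Prl3d2 these values therefore argue against a dye effect or a single array. Trophoblast tissue in the null pool would raise all 6 trophoblast markers. Of these 4 lay above 0 on all 4 arrays and 2 below, Plac1 (-0.46 ± 0.15) and Ascl2 (-0.16 ± 0.10), only 1 of them by more than 2 SD, so the test cannot tell. Prl3d1, among those above, is itself one of the prolactin genes that prompted the test. Trophoblast tissue, giant cells alone, which carry prolactin genes, and expression of these genes in the embryo stay open as hypotheses.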
